A study of Mus musculus with 15 samples.

How the data were processed

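RNA was measured in whole kidneys of mice, perfused with cold saline, in 15 libraries of 4 groups: Tert+/+ (WT) given vehicle (n = 4), WT given folic acid (n = 3), generation 3 Tert-/- (G3) given vehicle (n = 4) and G3 given folic acid (n = 4). Libraries were made with the QuantSeq kit, which reads the 3' end of polyadenylated transcripts and keeps the strand, per the labels' protocols. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, aligned to GRCm38 with TopHat2 2.0.10, Bowtie 1.0.0 and SAMtools 0.1.19, counted with HTSeq 0.6.1 and normalised with DESeq2. The annotation release, the strand setting of the counting and any filter on genes are not given in the sources used here.

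The deposited table holds 19602 genes by 15 libraries as a signal: gene counts that the authors divided by 1 size factor per library, per the file headers and from the values, which are whole multiples of a step of 0.895 to 1.13 in each library. Dividing by that step gave whole reads for 100 percent of values within 0.001, and library sizes of 5014684 to 6609307 reads (median 6091019). 1 read was therefore worth 0.895 to 1.13 normalised counts, and genes with a few reads per library carry large sampling error. Each library had a read in 18387 to 18905 genes. Of the symbols 19509 matched GENCODE M21, from which chromosomes, starts and ends were taken. Genes with near-identical copies (the Ugt2b, Cyp2 and Cyp4 families and the haemoglobin genes among them) may exchange reads, so their single values are less certain than those of their lists.

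Genes with a normalised count of at least 10 in at least 3 libraries were tested (14651 genes) on log2(normalised count + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, a term per group and a term for the labelled sex. p-values were adjusted by Benjamini-Hochberg (BH), with calls at adjusted p under 0.05. 6 comparisons were made: folic acid against vehicle in WT and in G3, G3 against WT after vehicle and after folic acid, the difference between the 2 folic acid effects, and labelled male against labelled female. All p-values measure the spread between libraries that the labels describe as separate animals. Numbers of replicates follow accession order and pair nothing. Because Xist and Y-linked RNA did not follow the labelled sex, each comparison was fitted again with the Y share of each library in place of that label. The Y share is the sum of Ddx3y, Kdm5d, Eif2s3y and Uty over that of the highest library, and this fit was chosen after the values were seen.

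35 fixed gene lists were written before the values were seen, covering fibrosis and epithelial programmes, injury, stress and immune genes, kidney cell types, metabolism, telomere and cell cycle genes, sex, time of day and tissues that dissection can carry along. The 32 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated from the data. Members were also counted after BH adjustment over the list alone. Genes were named by a fixed rule: the 8 largest changes each way among calls with a mean of at least 20 (5 each way for the interaction and 4 for sex), leaving out Y-linked genes, Xist and predicted gene models, the 3 members of smallest p in each list that passed, and a panel of Tert, Havcr1, Lcn2, Col1a1, Vim and Cdkn1a. A fold against a group without reads used a floor of 3 counts per library.

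Alternatives were leaving out each library, no sex term, libraries of 1 labelled sex only, the 2 compared groups only, other filters, pseudocounts of 0.5 and 5, TMM and quantile scaling, library weights, no trend, edgeR 4.0.16 and DESeq2 1.42.0 on the whole reads, and the series of title numbers as a term. Those chosen after the values were seen were the Y share fits, with edgeR, DESeq2, TMM, quantile scaling, without the 2 libraries that hold Xist and Y-linked RNA, and without WT folic acid 1, and the labelled sex fit without those 2 libraries. The procedure was tested on simulated data in which 50 genes each were changed 1.5, 2, 4 and 8-fold, up or down, in 1 group: limma recovered 10 to 24 percent at 1.5-fold in the 4 group comparisons, 44 to 74 percent at 2-fold and 94 to 96 percent at 4-fold, with 2.94 to 8.15 percent of calls false. For the interaction it recovered 0, 18, 70 and 88 percent, with 3.30 percent false, and DESeq2 had 11.1 to 13.1 percent false over all comparisons. Camera recovered a raised list in each comparison with both correlations and called 0 other lists. The simulated genes varied independently, with no sex difference and no outlying library, so these figures do not cover shared swings of real genes. All changed genes had a mean of at least 20, so the figures do not cover genes with fewer reads either. In other splits of the real libraries camera at the preset correlation called a median of 4 to 12 lists.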

Results

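Kidney RNA was compared between mice with telomerase (Tert+/+, here WT) and mice of the G3 generation bred without it (Tert-/-, here G3), in which telomeres have shortened over successive generations. Folic acid at 125 mg/kg, which injures kidney tubules and is followed by scarring, or its bicarbonate vehicle was injected once, and kidneys were taken at day 14. The 15 libraries read the 3' ends of polyadenylated RNA: 4 WT vehicle, 3 WT folic acid, 4 G3 vehicle and 4 G3 folic acid. Each held 5014684 to 6609307 reads assigned to genes (median 6091019), and 14651 genes were tested. Values are size-factor-normalised counts, and numbers such as WT folic acid 1 follow the order of the sample accessions only. The labels describe each library as a separate kidney. Each library was counted as 1 animal on that ground alone. The closest pairs of libraries, G3 vehicle 3 with 4 and WT folic acid 2 with 3, had a mean chi-square per gene of 2.98 and 3.29, against 8.16 for the next closest pair, and whether any pair came from 1 animal was not tested.

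Tert RNA was low in every group and did not separate the genotypes. Its normalised count was on average 12.1 (SD 8.65, n = 4) in WT vehicle, 9.002 (SD 3.99, n = 3) in WT folic acid, 8.30 (SD 5.20, n = 4) in G3 vehicle and 6.20 (SD 3.32, n = 4) in G3 folic acid. The G3 to WT difference was log2 0.13 after vehicle (SE 0.66, limma adjusted p = 0.951) with the labelled sex in the fit, against the direction of the group means, and log2 -0.39 without a sex term and -0.40 with the Y-linked RNA described below in its place. It was log2 -0.63 after folic acid (0.645-fold, SE 0.59, limma adjusted p = 0.587). Tert lies on chromosome 13 (start 73626911, end 73649843, GRCm38, GENCODE M21). The deleted part of Tert is not given in the sources used here and reads came from transcript 3' ends, so this level checks neither the deletion nor the labels.

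Xist, expressed from the inactive X chromosome, and the sum of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty placed 10 of the 15 libraries in the sex opposite to their label. Xist was 3147 to 5217 with a Y sum of 0.977 to 29.5 in 8 libraries, and the Y sum was 668 to 867 with Xist at 5.99 to 84.9 in 5 libraries, WT vehicle 1, 3 and 4 and G3 folic acid 1 and 3. The remaining 2 libraries held both kinds of RNA: WT vehicle 2 (Xist 3027, Y sum 283) and G3 folic acid 4 (Xist 2006, Y sum 273). Y-linked RNA therefore followed the groups, with a mean share of the highest library of 0.814 (SD 0.325) in WT vehicle and 0.476 (SD 0.378) in G3 folic acid, against 0.0205 in WT folic acid and 0.00567 in G3 vehicle. All 12 genes of a fixed list of genes higher in male mouse kidney followed the Y share adjusted over the list alone (8 over all genes), and none followed the labelled sex. Every comparison below was fitted with the labelled sex as a term, as set beforehand, and again with the Y share in its place, a fit added after the Xist and Y counts were seen. Because the Y share differed so much between groups, sex and group could not be fully parted by either fit.

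**Figure D1:**
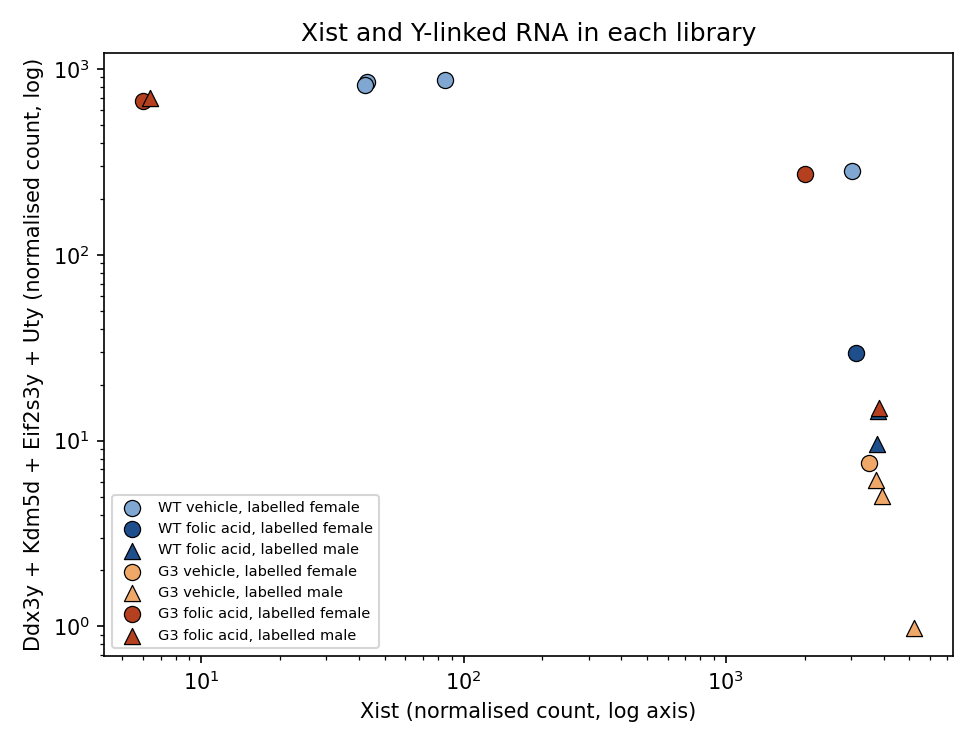
Xist against the summed Y-linked genes (Ddx3y, Kdm5d, Eif2s3y, Uty) in each of the 15 libraries, in normalised counts on log axes, with colour for the group and marker shape for the labelled sex. The 5 libraries at the upper left hold Y sums of 668 to 867, the 8 at the lower right hold Xist of 3147 to 5217, and 2 lie between with both RNAs.

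In kidneys labelled WT, folic acid was followed at day 14 by higher RNA of matrix and mesenchymal genes, to a large part in 1 of the 3 libraries. Fn1 (fibronectin) rose 5.94-fold (log2 2.57, SE 0.64, limma with BH adjusted p = 0.0478), from 48.5 (SD 20.8, n = 4) to 306 (SD 346, n = 3). Nid1 rose 3.12-fold (limma adjusted p = 0.0345), Sparc 3.01-fold (adjusted p = 0.0345) and Bgn 2.36-fold (adjusted p = 0.0470), all proteins of the matrix around cells. Zeb2, a transcription factor of epithelial to mesenchymal transition, rose 2.06-fold (limma adjusted p = 0.0371). Tagln and Cspg4, carried by contractile and pericyte-like cells, rose 2.37-fold and 2.04-fold (limma adjusted p = 0.0479 and 0.0345), and the endothelial receptor Eng rose 2.06-fold (adjusted p = 0.0209). WT folic acid 1 stood far above WT folic acid 2 and 3 in Fn1 (706 against 109 and 104), Sparc (4588 against 1357 and 1405) and Bgn (2060 against 796 and 841), while Eng (264, 245 and 221) was alike in all 3. All 4 WT vehicle libraries and WT folic acid 1 were labelled female, and WT folic acid 2 and 3 male. The labelled sex term therefore leaned these estimates towards WT folic acid 1. Without WT folic acid 1 limma called none of these 8 genes, with Fn1 at log2 1.13, Sparc at 0.75, Bgn at 0.66 and Eng at 1.11. Among 34 matrix genes 24 rose, adjusted over the list alone (5 over all genes), with a median of log2 1.30, or 0.25 without WT folic acid 1. Among 19 genes of epithelial to mesenchymal transition 8 rose and Cdh2 fell (log2 -1.27), adjusted over the list alone (4 and 0 over all genes).

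The same kidneys held less RNA of the fixed list of genes higher in male mouse kidney. Cyp2j13 fell 24.2-fold (limma adjusted p = 0.0345), Cyp4b1 12.8-fold (adjusted p = 0.0391), Cyp2e1 8.70-fold (adjusted p = 0.0345) and Odc1 4.05-fold (adjusted p = 0.0345). Of the 12 male kidney genes 10 fell adjusted over the list alone (6 over all genes), and all 3 female kidney genes, Slc7a12, Prlr and Cyp4a14, rose adjusted over the list alone (0 over all genes). Pzp, which is not on either list, fell 39.6-fold (log2 -5.31, SE 0.58, limma adjusted p = 0.00152), from 354 (SD 112, n = 4) to 6.94 (SD 3.19, n = 3). Its RNA also went with Y-linked RNA, at 77.8 to 444 in every library with a Y sum over 100. In the other libraries Pzp was 3.01 to 10.6, except for 43.2 in G3 folic acid 2. WT vehicle held the most Y-linked RNA of the groups and WT folic acid almost none, and with the Y share in the fit the only gene still called was Pzp (log2 -3.56, limma adjusted p = 0.0347). Fn1 was then log2 1.17 (limma adjusted p = 0.981) and Sparc log2 0.77 (adjusted p = 0.981).

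In total 370 genes passed in this comparison (191 higher, 179 lower), and 1 passed with the Y share in the fit. The balance depended on the tool, with 306 higher and 150 lower in edgeR. With the series of title numbers as a term, a possible batch that the labels do not name, limma called 5. The series nearly repeat the groups. One holds G3 vehicle 1 to 3 alone, another WT vehicle 1 to 3 with all WT folic acid. The last holds all G3 folic acid with WT vehicle 4 and G3 vehicle 4. Outside folic acid in WT, that fit rests on WT vehicle 4 or G3 vehicle 4, so lost calls there cannot tell batch from group. For 19.9 percent of genes the WT vehicle and WT folic acid libraries did not overlap, against 5.71 percent expected by chance. Leaving out WT folic acid 1, which carried 23.0 percent of its reads in the single gene Gm42418 (4.85 to 8.15 percent elsewhere), left 1 gene called, and leaving out WT vehicle 1, 3 or 4 left 12, 5 and 4. Without WT folic acid 2 or 3 the count was 123 and 21, and without WT vehicle 2, with both sexes' RNA, it was 886. The tubular injury genes Havcr1 (4.48-fold, limma adjusted p = 0.257) and Lcn2 (6.68-fold, adjusted p = 0.169) and the collagen Col1a1 (3.71-fold, log2 1.89, SE 0.62) did not pass over all genes. In WT folic acid 1, 2 and 3 Havcr1 was 44.2, 4.80 and 0.953, Lcn2 was 358, 11.5 and 12.4, and Col1a1 was 1769, 178 and 214, with vehicle means of 2.29, 11.9 and 165. Vim rose 1.76-fold without passing (limma adjusted p = 0.158) and the p53 target Cdkn1a did not pass (0.993-fold, adjusted p = 0.992). Cdkn1a was 244 (SD 35.5, n = 4) in WT vehicle and 284 (SD 37.8, n = 3) in WT folic acid, log2 0.22 without a sex term and 0.32 with the Y share, and limma called it in neither fit.

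Of 32 gene lists tested with camera at a preset correlation of 0.01, 11 passed in WT. Higher were matrix (limma camera adjusted p = 5.78e-14), transition (0.000156), tubular injury (0.00340), interferon (0.000232), macrophage (0.000183), fibroblast and pericyte (0.00340), endothelial (0.00329) and female kidney genes (0.00802). Lower were proximal tubule (0.0495), oxidative phosphorylation (0.00340) and male kidney genes (1.89e-09). No list kept its call when the correlation was estimated: the smallest adjusted p = 0.501 with an estimated correlation, so a shared swing of each list in single animals was not excluded. At the preset correlation 6 lists passed with the Y share and 5 of the 11 were kept: matrix, transition, macrophage, endothelial and male kidney genes. Tubular injury (limma camera adjusted p = 0.0534), interferon (0.158), fibroblast and pericyte (0.138), proximal tubule (0.601), oxidative phosphorylation (0.908) and female kidney genes (0.222) were not. Without WT folic acid 1 the calls ended for transition (median log2 0.17), tubular injury (-0.04), interferon (0.15), fibroblast and pericyte (0.26), proximal tubule (0.24) and oxidative phosphorylation genes (-0.17), and the macrophage list passed as lower (-0.40), while matrix genes still passed as higher (0.25). The proximal tubule call also ended without WT vehicle 2 or 4 (-0.32 and -0.31), G3 vehicle 2 or 4 (-0.37 and -0.41) or G3 folic acid 4 (-0.42), and held in 9 of 15 fits. Members that rose adjusted over the list alone were 6 of 14 fibroblast and pericyte genes (2 over all genes), 3 of 15 endothelial genes (1 over all genes), 2 of 22 interferon genes (Gbp3 and Mx2), 1 of 18 tubular injury genes (Spp1) and 0 of 19 macrophage genes. In oxidative phosphorylation 3 of 24 genes fell adjusted over the list alone, Ndufb5, Atp5c1 and Atp5o (0 over all genes).

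In kidneys labelled G3, folic acid was followed by higher RNA of genes of macrophages, tubular injury and dividing cells. Fcgr1, a macrophage Fc receptor, had no read in any of the 4 G3 vehicle libraries and a mean of 28.1 (SD 8.56, n = 4) after folic acid, at least 9.18-fold higher with a floor of 3 counts per library (limma adjusted p = 0.00194, with the Y share 0.00505). Il34, a macrophage growth factor made by injured tubules, rose 3.54-fold (log2 1.82, SE 0.31, limma adjusted p = 0.0439), from 75.9 (SD 17.6, n = 4) to 302 (SD 80.0, n = 4). It was not called with the Y share. Il34 was 180 to 304 in WT vehicle, where all libraries held Y-linked RNA, and 61.5 to 101 in G3 vehicle, which held almost none. With almost no Y-linked RNA it was 195 in G3 folic acid 2 and 296, 98.9 and 77.2 in WT folic acid 1, 2 and 3. Cenpf, expressed by cells in mitosis, rose 3.08-fold (log2 1.62, SE 0.29, limma adjusted p = 0.0475, with the Y share 0.0363). Of 19 macrophage genes 18 rose adjusted over the list alone (1 over all genes), C1qb by 4.22-fold and Itgam by 4.91-fold. Of 18 tubular injury genes 11 rose adjusted over the list alone (1 over all genes), among them Havcr1, Lcn2, Vcam1, Timp1 and Clu.

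Matrix genes rose in G3: 23 of 34 adjusted over the list alone (0 over all genes), with Col1a1 at 943 (SD 271, n = 4) against 208 (SD 105, n = 4), 4.20-fold (log2 2.07, SE 0.52, limma adjusted p = 0.124 over all genes). Among the 19 transition genes 8 rose and Acta2 fell (log2 -0.54), adjusted over the list alone (0 over all genes). Of 17 proliferation genes 7 rose adjusted over the list alone, Mki67, Top2a, Cdc20, Birc5, Cenpf, Nusap1 and Kif11 (1 over all genes). Havcr1 was 22.0 to 80.8 in the 4 G3 folic acid libraries and 0 to 9.02 in G3 vehicle (16.5-fold, log2 4.05, SE 0.91), and Lcn2 rose from 16.2 to 148 (6.89-fold), but over all genes limma adjusted p = 0.116 and 0.231. The transition genes Zeb2 (log2 0.77), Fn1 (1.93), Mmp14 (1.46), Tgfbi (0.97) and Sparc (0.96) rose in both genotypes adjusted over the list alone.

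Slc10a2, Hpd, Insr and erythroid genes were lower after folic acid in G3. Slc10a2, a bile acid transporter of the tubule, fell 2.12-fold (log2 -1.08, SE 0.15, limma adjusted p = 0.00672, with the Y share 0.0268), from 590 (SD 55.8, n = 4) to 280 (SD 54.3, n = 4). Hpd, an enzyme of tyrosine breakdown, fell 3.94-fold (log2 -1.98, SE 0.33, limma adjusted p = 0.0439) and the insulin receptor Insr 1.57-fold (log2 -0.65, SE 0.11, adjusted p = 0.0439). Neither Hpd nor Insr was called with the Y share. Hpd was 75.8 to 254 in WT vehicle, which held Y-linked RNA, against 233 to 632 in G3 vehicle, which held almost none. All 5 erythroid genes fell adjusted over the list alone (0 over all genes). Among them the haemoglobin gene Hba-a2 was 2.76-fold lower (log2 -1.46, limma adjusted p = 0.0685) and Alas2, the enzyme that starts haem synthesis in red cells, 2.91-fold lower (log2 -1.54, adjusted p = 0.0551). With the Y share in the fit both passed over all genes (limma adjusted p = 0.00120 for each). Of 5 neutrophil genes 3 fell adjusted over the list alone, S100a8, S100a9 and Retnlg.

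Male kidney genes moved the other way than in WT: 10 of 12 rose adjusted over the list alone (0 over all genes), while the 3 female kidney genes fell. Y-linked RNA was present in 3 of 4 G3 folic acid libraries and almost absent from G3 vehicle. Of genes on neither list, Pzp rose 17.3-fold (log2 4.11, SE 0.48, limma adjusted p = 0.00194, with the Y share 0.00208), Ugt2b37 rose by log2 4.25 (adjusted p = 0.0442, with the Y share 0.285). Pzp was 43.2 in G3 folic acid 2, which held Xist and almost no Y-linked RNA, and 77.8 to 301 in the other G3 folic acid libraries, which held Y-linked RNA. In total 12 genes passed (8 higher, 4 lower), 9 passed with the Y share, and 4 passed in both fits: Fcgr1, Cenpf, Pzp and Slc10a2. None of the 12 stayed called with the Y share and without the 2 libraries of mixed RNA (limma adjusted p = 0.257, 0.848, 0.183 and 0.649 for these 4). The Y term of that fit rests largely on G3 folic acid 2 against 1 and 3 (Y share 0.0173 against 0.800 and 0.771). With the title number series as a term limma called 0 (537 at unadjusted p under 0.05). Non-overlapping genes made up 7.75 percent, against 2.86 percent expected by chance. The count ranged from 2 without G3 vehicle 3 to 275 without WT folic acid 1, and was 158 and 166 without G3 folic acid 2 or 3, so the number of genes depended on single animals.

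In camera 18 of 32 lists passed in G3. Higher were macrophage (limma camera adjusted p = 4.58e-21), matrix (6.55e-20), tubular injury (2.03e-10), male kidney (8.75e-13), proliferation (2.70e-09), inflammatory (1.11e-08), transition (6.61e-06), interferon (2.70e-05), T and NK cell (0.000599), p53 target (0.00513) and senescence genes (0.00777). Lower were erythroid (3.88e-09), collecting duct (0.000599), neutrophil (0.000776), fatty acid oxidation (0.00129), female kidney (0.00174), urothelium (0.00777) and adipose genes (0.0398). The smallest adjusted p = 0.112 with an estimated correlation, reached by macrophage, matrix, tubular injury and proliferation genes. At the preset correlation 13 of the 18 were kept with the Y share, where 18 lists passed in all, and p53 target (limma camera adjusted p = 0.111), senescence (0.0706), collecting duct (0.0507), female kidney (0.876) and urothelium genes (0.0700) were not. Erythroid genes then passed with an estimated correlation as well (limma camera adjusted p = 0.0364). Leaving out each of the 15 libraries in turn ended no call among macrophage (median log2 at least 1.29), matrix (0.77 to 1.14), tubular injury (0.83 to 1.23), proliferation (0.81 to 1.45), inflammatory (0.57 to 0.95), transition (0.50 to 0.89) and erythroid genes (-1.71 to -1.24). Calls ended for senescence genes without G3 folic acid 1 or 2 (median log2 0.27 and 0.58), for fatty acid oxidation without G3 folic acid 2 (-0.10), for urothelium without G3 vehicle 1 or 3 or G3 folic acid 3 (-0.54, -0.98 and -0.90), and for adipose genes without G3 vehicle 1 or G3 folic acid 1, 2 or 4 (-0.12, -0.54, -0.87 and -0.73). Of the inflammatory genes 6 of 14 rose adjusted over the list alone, Ccl5, Cxcl16, Il1b, Il34, Vcam1 and Nfkb2 (1 over all genes). Few members carried the p53 target (Gdf15, 1 of 21), senescence (0 of 14), interferon (0 of 22), T and NK cell (Trbc2, 1 of 9), collecting duct (Aqp4, 1 of 14), fatty acid oxidation (Hadhb and Ppargc1a, 2 of 21), urothelium (Krt5, 1 of 6) and adipose (0 of 5) calls adjusted over the list alone.

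**Figure D2:**
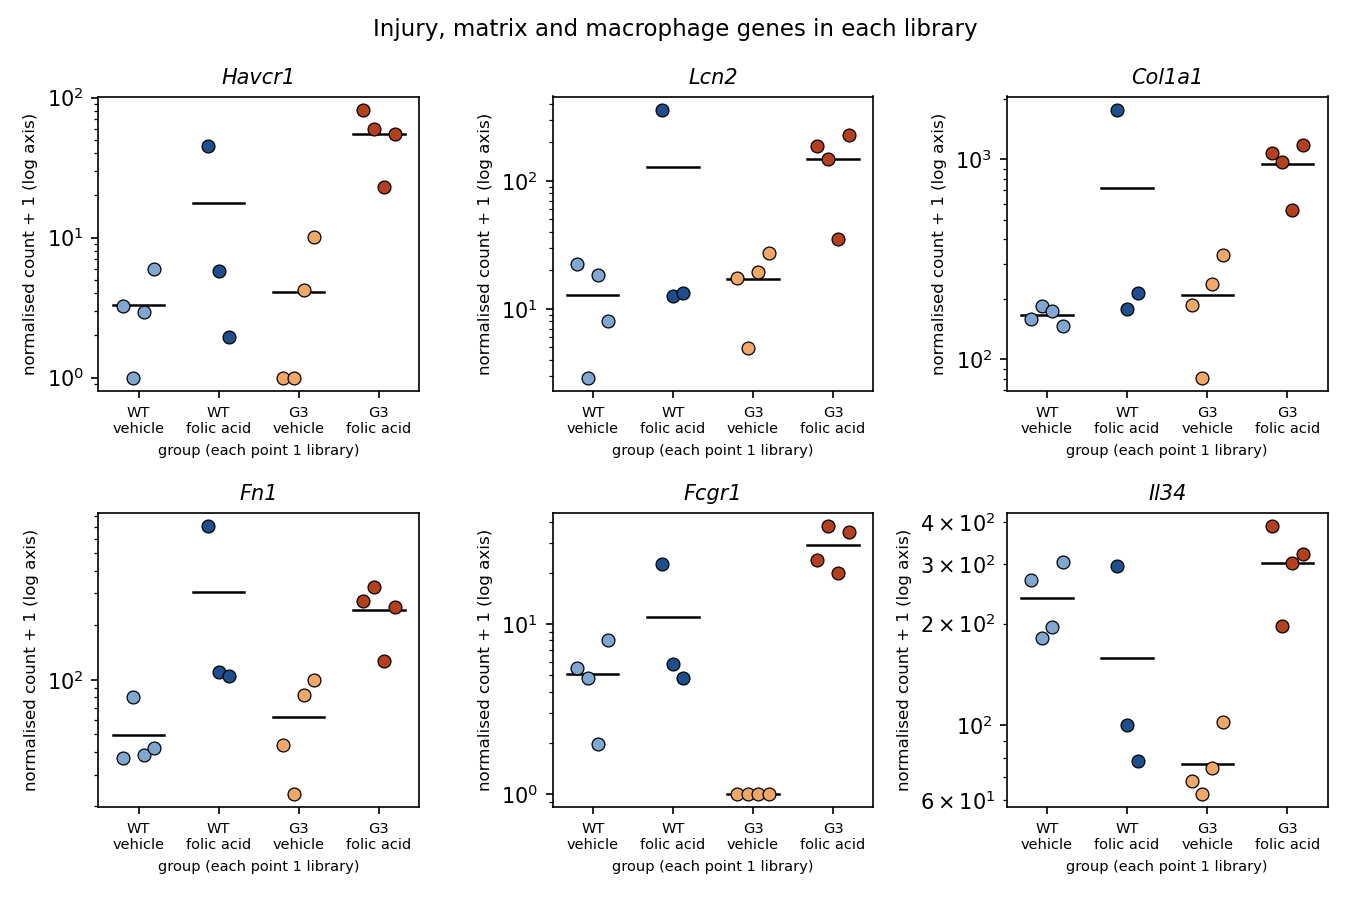
Havcr1, Lcn2, Col1a1, Fn1, Fcgr1 and Il34 in each library (points) by group, normalised count plus 1 on a log axis, with bars at group means. All 4 G3 folic acid libraries lie above G3 vehicle in each gene, whereas WT folic acid 1 lies above the other 2 WT folic acid libraries, with Havcr1 at 44.2 against 4.80 and 0.953 and Col1a1 at 1769 against 178 and 214. Fn1 is above every WT vehicle library in all 3 (706, 109 and 104), and Il34 is not (296, 98.9 and 77.2 against 180 to 304).

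Between the genotypes after vehicle alone, male kidney genes were lower and female kidney genes higher in the kidneys labelled G3, which held Xist and almost no Y-linked RNA. Cyp2j13 was 45.4-fold lower (limma adjusted p = 0.0409), and 11 of 12 male kidney genes fell adjusted over the list alone (1 over all genes). Of genes on neither list, Pzp was 46.4-fold lower (log2 -5.54, SE 0.57, limma adjusted p = 0.000623, with the Y share 0.0129), 5.60 (SD 2.06, n = 4) against 354 (SD 112, n = 4), and Ugt2b37 29.5-fold lower (adjusted p = 0.0409). Erc2 (2.75-fold), Kif20b (5.24-fold) and Csgalnact1 (3.70-fold, all limma adjusted p = 0.0248) and Chst11 (7.40-fold, adjusted p = 0.0300) were lower, and the ephrin ligand Efnb2 was the only gene called higher (2.06-fold, log2 1.04, SE 0.19, adjusted p = 0.0409). None of the 5 genes from Erc2 to Efnb2 passed with the Y share (limma adjusted p = 0.766 to 0.803).

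Of 13 circadian genes 6 were higher in G3 vehicle, among them Dbp (log2 2.19), Per2 (1.79) and Ciart (3.01), and 3 were lower, Arntl (-2.68), Npas2 (-2.44) and Clock (-0.47), adjusted over the list alone (0 over all genes). Kidneys taken at another hour of the day give such a pattern, and the hour is not given in the sources used here. Ciart was 17.0 to 18.4 in G3 vehicle 3 and 4 but 5.86 to 7.12 in G3 vehicle 1 and 2, and lower in each WT vehicle library. Of 5 adipose genes 4 were higher adjusted over the list alone (Adipoq, Cidec, Fabp4 and Retn), with Adipoq at 297 in G3 vehicle 1 and 4.01 to 32.5 in the other 3. Of 18 tubular injury genes Spp1 was higher (log2 1.26) and Il34 lower (-1.21) in G3 vehicle adjusted over the list alone (0 over all genes), and the list did not pass (median log2 0.42, limma camera adjusted p = 0.0923). Y-linked RNA differed between these groups in the same direction as Il34, so the Il34 value cannot be fully parted from sex. Not called were Havcr1 (1.51-fold, limma adjusted p = 0.842), Lcn2 (2.64-fold, adjusted p = 0.608), Col1a1 (1.78-fold, adjusted p = 0.579) and Vim (1.27-fold, adjusted p = 0.674). Simulation recovered 48 percent of 2-fold changes in this comparison among genes with a mean of at least 20, a mean that Havcr1 did not reach. Cdkn1a was 0.796-fold (limma adjusted p = 0.717) with the labelled sex in the fit, log2 -0.07 without a sex term and 0.03 with the Y share. Its mean was 263 (SD 148, n = 4) in G3 vehicle, with 411 and 370 in libraries 1 and 2 and 129.8 and 142 in 3 and 4, against 244 (SD 35.5, n = 4) in WT vehicle.

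In total 17 genes passed after vehicle (1 higher, 16 lower) and 1, Pzp, passed with the Y share. Without the 2 libraries of mixed RNA Pzp was not called with the Y share either (limma adjusted p = 0.929), nor any other of the 17. The Y term of that fit rests largely on differences within G3 folic acid. With the title number series as a term limma called 0 (937 at unadjusted p under 0.05). Non-overlapping genes made up 11.01 percent, against 2.86 percent by chance. The count was 1 without WT vehicle 1, 3 or 4 and without G3 vehicle 3, 2 without G3 vehicle 2, 10 without G3 vehicle 4, 127 without WT vehicle 2 and 41 without G3 vehicle 1. Camera passed 7 lists: higher were matrix (limma camera adjusted p = 0.000557), female kidney (0.00111), adipose (0.00227), circadian (0.00512), fibroblast and pericyte (0.0241) and endothelial genes (0.0241), and lower were male kidney genes (2.27e-13). For these the smallest limma camera adjusted p = 0.418 with an estimated correlation. With the Y share 4 lists passed at the preset correlation. Of the 7, 2 were among them, adipose and male kidney genes, and matrix (limma camera adjusted p = 0.675), female kidney (0.820), circadian (0.316), fibroblast and pericyte (0.857) and endothelial genes (0.625) were not. No matrix gene (0 of 34) and no fibroblast and pericyte gene (0 of 14) passed adjusted over the list alone, and of 15 endothelial genes Plvap and Plat did. With the Y share the matrix median was log2 -0.14, against 0.51 with the labelled sex and 0.14, no longer passing, without WT folic acid 1. The fibroblast and pericyte call ended without WT vehicle 4, WT folic acid 1 or G3 vehicle 1 (0.35, 0.23 and 0.34), and the endothelial call without WT vehicle 4 or G3 vehicle 1 (0.19 and 0.17).

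After folic acid, kidneys labelled G3 differed from WT in single genes and in 7 lists, male kidney genes among them, at the preset correlation. None of the 7 passed at an estimated one, and no list of proximal tubule, loop or collecting duct genes passed. Npnt, a matrix protein of the collecting duct, was 3.82-fold lower in G3 (log2 -1.93, SE 0.31, limma adjusted p = 0.00983, with the Y share 0.0125), 1001 (SD 391, n = 4) against 3580.2 (SD 285, n = 3). Aqp4, the water channel of the same cells, was 5.12-fold lower (log2 -2.36, SE 0.35, limma adjusted p = 0.00636, with the Y share 0.0927) and Zbtb16, a transcription factor induced by glucocorticoids, 8.09-fold lower (log2 -3.02, SE 0.44, adjusted p = 0.00555, with the Y share 0.0927). The endothelial receptors Flt1 and Eng were 1.49-fold and 1.61-fold lower (limma adjusted p = 0.0265 and 0.0329), 2 of 15 endothelial genes adjusted over the list alone (2 over all genes). The mitochondrial transfer RNA gene mt-Tp was 4.10-fold lower (limma adjusted p = 0.00218), at 225 to 280 in WT folic acid and 36.3 to 123 in G3 folic acid, with 46.9 to 88.7 in all vehicle libraries.

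Higher in G3 after folic acid were Pzp (14.7-fold, log2 3.88, SE 0.51, limma adjusted p = 0.00249, with the Y share 0.00682), Cyp2d9 (5.49-fold, log2 2.46, adjusted p = 0.0208, with the Y share 0.00776), Cyp2e1 (7.72-fold, adjusted p = 0.0265) and Nat8f5 (7.38-fold, adjusted p = 0.0329). Of 12 male kidney genes 10 were higher adjusted over the list alone (2 over all genes). Of 18 tubular injury genes 3 were higher adjusted over the list alone, Cd44 (log2 1.68), Gdf15 (0.76) and Il34 (1.06), and of 14 inflammatory genes Ccl5, Il34 and Nfkbia (0 over all genes for both lists). Havcr1 was 5.57-fold higher (53.7, SD 24.2, n = 4, against 16.7, SD 24.0, n = 3, limma adjusted p = 0.171), Lcn2 2.72-fold (adjusted p = 0.440) and Col1a1 2.01-fold (adjusted p = 0.323), so none of these 3 was called over all genes, while the tubular injury list passed as higher in G3 at the preset correlation (median log2 0.78) and did not at an estimated one (limma camera adjusted p = 0.000873 and 0.682).

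In total 268 genes passed after folic acid (79 higher, 189 lower in G3), 17 passed with the Y share and 15 in both fits. With the title number series as a term, a possible batch that the labels do not name, limma called 0 (630 at unadjusted p under 0.05), but no series holds both of these groups. Non-overlapping genes made up 17.3 percent, against 5.71 percent by chance. The count was 35 and 20 without WT folic acid 2 or 3, 20, 410 and 96 without G3 folic acid 1, 2 or 3, and 327 without WT folic acid 1. Camera passed 7 lists: higher were male kidney (limma camera adjusted p = 3.76e-07), inflammatory (0.000299), macrophage (0.000299), tubular injury (0.000873) and adipose genes (0.0162), and lower were erythroid (0.0299) and endothelial genes (0.0427). The smallest limma camera adjusted p = 0.682 with an estimated correlation. With the Y share 9 lists passed at the preset correlation. Of the 7, 6 were among them, and endothelial genes were not (limma camera adjusted p = 0.104). Adjusted over the list alone 0 of 19 macrophage genes, 3 of 5 adipose genes (Cfd, Cidec and Retn) and 2 of 5 erythroid genes (Hba-a2 and Alas2, both lower) passed. Tubular injury, inflammatory and male kidney genes passed without each library in turn. Among female-labelled libraries the macrophage median was log2 -1.07, but there WT folic acid is WT folic acid 1 alone, so this restates how high that library was. The macrophage call ended without WT folic acid 3 (median log2 0.62), the adipose call without WT folic acid 1 or G3 folic acid 3 (1.71 and 1.67), the erythroid call without G3 folic acid 2 or 4 (-0.41 and -0.29), and the endothelial call in 6 of the 15 fits (-0.38 to -0.12 over all 15).

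**Figure D3:**
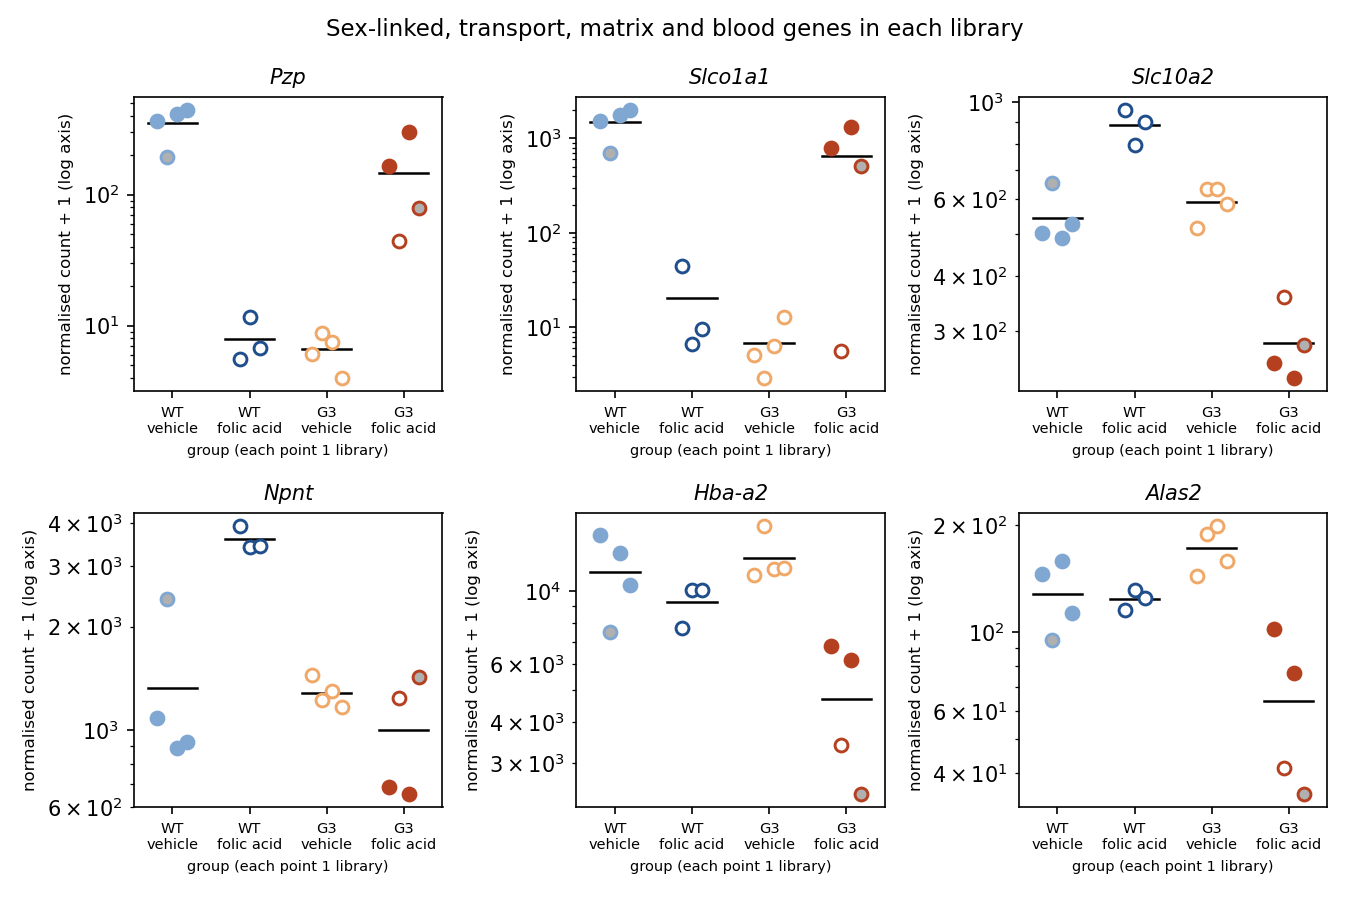
Pzp, Slco1a1, Slc10a2, Npnt, Hba-a2 and Alas2 in each library (points) by group, normalised count plus 1 on a log axis, with bars at group means: filled points are the 5 libraries with Y-linked RNA and little Xist, open points the 8 with Xist alone and grey points the 2 with both. Slco1a1 follows the fill. Pzp was 77.8 to 444 in the filled and grey libraries, 43.2 in the open G3 folic acid library and 3.01 to 10.6 in the other open ones. Slc10a2 was 234 to 357 in G3 folic acid and 488 to 958 in the other 11.

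The change with folic acid differed between the genotypes for 103 genes, 55 more positive and 48 more negative in G3. With the title number series as a term limma called 4. The male kidney genes Slco1a1 (log2 9.87, SE 1.79, limma adjusted p = 0.0201), Slc7a13 (9.01, adjusted p = 0.0257), Cyp2j13 (8.87, adjusted p = 0.00941) and Odc1 (3.30, adjusted p = 0.0173) changed more positively in G3, and none of these 4 passed with the Y share. Pzp, on neither sex list, changed by log2 9.42 more in G3 (SE 0.80, limma adjusted p = 3.87e-05), and with the Y share by 6.60 (adjusted p = 0.00221). Pzp RNA went with Y-linked RNA in every library but G3 folic acid 2, so its change is not shown to be free of sex. With the Y share and without the 2 libraries of mixed RNA, limma called no gene in this comparison. Ceacam2 (log2 -4.64, limma adjusted p = 0.0169), Hsd17b14 (-4.51, adjusted p = 0.0294), Padi2 (-4.42, adjusted p = 0.0193), Zbtb16 (-3.92, adjusted p = 0.0172) and Hao2 (-3.47, adjusted p = 0.0257) changed the other way, and none of these 5 passed with the Y share (log2 -1.07, -0.89, -1.69, -3.11 and -0.79). All 12 male kidney genes rose more in G3 (8 over all genes) and all 3 female kidney genes less, adjusted over the list alone.

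The tubular injury and matrix lists did not pass for a different change (limma camera adjusted p = 0.449 and 0.276), and adjusted over the list alone Il34 did (log2 2.27, 1 of 18 tubular injury genes) and 0 of 34 matrix genes. Il34 differed between the vehicle groups as Y-linked RNA did, so its value here cannot be fully parted from sex. Both lists passed with the Y share as more positive in G3 at the preset correlation (median log2 0.63 and 0.60, limma camera adjusted p = 0.00452 and 0.00215) and neither did at an estimated one (0.856 for each). Simulation recovered 18 percent of 2-fold changes in this comparison among genes with a mean of at least 20, so a missing call leaves a difference open. The difference was log2 1.88 (SE 1.499, limma adjusted p = 0.615) for Havcr1, 0.04 (SE 1.54, adjusted p = 0.992) for Lcn2 and 0.18 (SE 0.85, adjusted p = 0.949) for Col1a1. Camera passed 5 lists: more positive in G3 were male kidney (adjusted p = 3.40e-17) and macrophage genes (0.0456), and more negative were female kidney (0.000545), endothelial (0.000930) and erythroid genes (0.0456), and the smallest adjusted p = 0.361 with an estimated correlation. With the Y share 9 lists passed at the preset correlation. Of the 5, 3 were among them, and female kidney (limma camera adjusted p = 0.497) and endothelial genes (0.0526) were not. Erythroid genes then passed with an estimated correlation too (median log2 -2.98, adjusted p = 0.0264), and Alas2 passed over all genes (log2 -3.19, limma adjusted p = 0.0426). Male kidney, female kidney and endothelial genes passed without each library in turn, whereas macrophage genes passed in 6 of those 15 fits (median log2 0.29 to 2.18) and erythroid genes in 9 (-1.37 to -0.37). Among female-labelled libraries the macrophage median was log2 -0.91, but there WT folic acid is WT folic acid 1 alone and G3 vehicle is G3 vehicle 3 alone. Adjusted over the list alone 1 of 19 macrophage genes (Fcgr1, log2 3.42), 1 of 15 endothelial genes (Eng, -0.93) and 1 of 5 erythroid genes (Alas2, -1.47) passed. With the Y share 2 genes passed over all genes, and leaving out 1 library moved the 103 to between 6 (G3 vehicle 3) and 570 (G3 folic acid 2), with 14 without WT folic acid 1 and 439 without WT vehicle 2.

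Labelled sex called 0 genes in limma, with 654 genes at unadjusted p under 0.05, and 0 in edgeR and 0 in DESeq2. The Y-linked genes Ddx3y (log2 -1.63, SE 0.75), Eif2s3y (-1.64, SE 0.76) and Uty (-1.54, SE 0.69) were lower, not higher, in libraries labelled male, with limma adjusted p = 0.994 for each, and Xist did not differ (log2 0.37, SE 1.61). The Y share called 190 genes, 107 higher and 83 lower with more Y-linked RNA.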

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

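The tests of labels exchanged throughout, of stray Y-linked reads, of mixed RNA, of an extra X chromosome and of the Gm42418 share were chosen only after the result was seen; the placement of each library by genotype was written before it was run.

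Xist and Y-linked RNA went against the labelled sex in 10 of 15 libraries. An exchange of male and female in every label would leave no match, and 3 libraries with 1 kind of RNA matched. Stray Y-linked reads would leave male kidney RNA where it was, and 12 of 12 male kidney genes followed the Y share adjusted over the list alone. Columns exchanged between the genotypes stayed open: with each library left out of the choice of genes, the lowest share of genotype-separating genes in which it lay nearer its own genotype was 31.3 percent (G3 vehicle 1), with 35.3 percent for WT folic acid 1, 49.0 percent for G3 folic acid 3 and 50.9 percent for WT vehicle 3. A wrong sex entered for each of the 10 animals cannot be told apart from such exchanges, because no value here carries the identity of an animal.

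In WT vehicle 2 and G3 folic acid 4, Xist and Y-linked RNA occurred together. Mixed male and female kidney RNA would give Y and Xist fractions that add up to about 1, and the sums were 1.15 and 0.868, with Y fractions of 0.363 and 0.350 and male kidney genes at 0.410 and 0.358 of the male level. An animal with 2 X and 1 Y chromosome in every cell would hold Y-linked RNA near the male level, and the fractions of 0.363 and 0.350 argue against that. A mixture at some step from tissue to library may therefore explain both libraries, and no biological explanation was tested beyond an extra X in every cell.

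Injury and matrix genes were high in 1 of 3 WT folic acid libraries. Through lost read share, the 23.0 percent of its reads in Gm42418 could shift other genes by at most log2 0.26. The 51 injury and matrix genes were shifted by a median of log2 1.57 from the other WT folic acid libraries, 48 of them upward. Whether RNA quality differed in this library was not tested, as the labels give only a range for all (4.7 to 8.0, mean 6.3). A G3 folic acid library under a WT label stayed open, since this library lay nearer the WT mean in 35.3 percent of separating genes. A stronger response to folic acid in 1 animal, with Havcr1 at 44.2, cannot be told apart from that, because the group has no other animal like it. WT folic acid 2 and 3 lay near the WT vehicle means in Havcr1 (4.80 and 0.953 against 2.29) and Lcn2 (11.5 and 12.4 against 11.9). In Fn1 (109 and 104) and Eng (245 and 221) they lay above every WT vehicle library. Whether WT folic acid 2 and 3 came from animals with little response, or from columns exchanged between treatments, was not tested.

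The number of genes called was set against other splits of the same libraries, with the labelled sex kept with each library. No other split of 35 called as many genes for folic acid in WT (370 genes, highest other split 322) or for G3 against WT after folic acid (268, highest other 246). For the interaction (103, highest other 279, genotype permuted in 100 draws) 3 gave as many, the real one counted. These shares were not adjusted over the comparisons, and 1 of 35 is the smallest share possible, so chance is not excluded. The 322 genes came from WT vehicle 1, 3 and 4 against the rest and the 246 from WT folic acid 1 to 3 with G3 folic acid 2 against the rest, both of which are splits by Y-linked RNA. After folic acid 2 further splits that differed little in Y share came near the real count: WT folic acid 1 with G3 folic acid 1, 2 and 4 against the rest (233 genes, difference 0.0253), and WT folic acid 2 and 3 with G3 folic acid 3 and 4 against the rest (180 genes, -0.00547). Nor can chance be excluded for folic acid in G3 (12 genes, highest other 73, 3 of 35 splits as large) or for G3 against WT after vehicle (17, highest other 53, 2 of 35). For labelled sex the real count was 0, which every split reaches (72 of 72, highest other 3), so that test could decide nothing. A split with several times the real count points to a structure of the libraries other than the groups. For lists, chance cannot be excluded in any comparison: 11 lists against a highest other of 20 (23 of 35 splits as large), 18 against 23 (8 of 35), 7 against 16 (13 of 35), 7 against 19 (23 of 35) and 5 against 20 (81 of 100).

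Genes named in the text and some library measures were checked in each group of 4 libraries, which leaves out WT folic acid (n = 3). Many of these genes vary together and counts were not logged, so the number to expect by chance is not known. In 41 of 317 such checks 1 library lay far from the other 3, against 15.9 for independent, normally spread values. In WT vehicle 2, which holds both sexes' RNA, these were Xist (3027, nearest other 84.9), the Y sum (283, nearest 816), Ddx3y (150, nearest 413), Uty (70.1), Prlr (1597), Slc7a12 (293), Slc7a13 (999), Cyp4a14 (547), Cyp2d9 (237), Ceacam2 (159), Npnt (2407), Zbtb16 (104), Gbp3 (97.6), Fn1 (79.6), Cdh2 (31.3), Mki67 (54.0), Efnb2 (61.6), Flt1 (726) and Insr (292). In G3 vehicle 1 they were Adipoq (297, nearest 32.5), Cfd (1518), Cidec (126), Fabp4 (1272), Retn (214), Acta2 (377), Ccl5 (33.6), Flt1 (747) and Nat8f5 (2.03), and in G3 folic acid 3 Adipoq (43.0), Cfd (294), Cidec (37.96), Retn (46.0) and Spp1 (982, nearest 2366). Single libraries far from their group were WT vehicle 1 for Ccl5 (7.92), G3 vehicle 2 for Cyp2e1 (219), Cyp4a14 (2861), Hba-a2 (15806.5) and Ppargc1a (833), G3 vehicle 4 for Nfkbia (595), G3 folic acid 1 for S100a9 (31.8) and G3 folic acid 2 for Gm42418 (7.80 percent of reads).

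The folic acid effect differed between the genotypes, by the test of the difference, for 103 genes. Among the genes named these were Slco1a1 (log2 9.87), Pzp (9.42), Slc7a13 (9.01), Cyp2j13 (8.87), Ugt2b37 (8.40) and Odc1 (3.30), and in the other direction Ceacam2 (-4.64), Hsd17b14 (-4.51), Padi2 (-4.42), Zbtb16 (-3.92) and Hao2 (-3.47). With the Y share 2 genes were called and Pzp alone of the 103 was kept, and without the 2 libraries of mixed RNA Slco1a1 (-2.56), Slc7a13 (-2.81), Cyp2j13 (-0.71) and Ugt2b37 (-0.51) went the other way in that fit. Lists that passed at the preset correlation were male kidney (median log2 5.81), female kidney (-5.93), macrophage (0.75), endothelial (-0.51) and erythroid genes (-0.93). With an estimated correlation 0 lists passed (smallest limma camera adjusted p = 0.361), and with 1 library left out macrophage genes passed in 6 of 15 fits and erythroid genes in 9.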

How the results depend on the processing

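The Y share fits and the labelled sex fit without the 2 libraries of mixed RNA were chosen after the result was seen, and the other settings before. Counts below follow the order folic acid in WT, folic acid in G3, G3 against WT after vehicle, G3 against WT after folic acid, interaction, with 370, 12, 17, 268 and 103 genes by limma with the labelled sex. All 370, 12, 17, 268 and 103 genes kept their sign with the Y share, and their median absolute log2 fell from 1.21 to 0.63, 2.74 to 2.37, 2.89 to 1.59, 0.96 to 0.79 and 2.78 to 1.07. Labelled sex called 0 genes by limma, edgeR and DESeq2 (654, 607 and 532 unadjusted). No paired analysis was possible because the replicate numbers follow accession order and mark no shared animal, litter or day. Read depth limits genes with few reads, since 1 read is worth 0.895 to 1.13 normalised counts. Where a count moved, the cause was not tested unless named.

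TMM scaling and pseudocounts of 0.5 and 5 left each count within 1.5 times. Other settings gave 741, 40, 425, 337 and 560 genes without a sex term, 1175, 19, 59, 161 and 252 from female-labelled libraries only (where WT folic acid and G3 vehicle hold 1 library each, so every comparison has a group without replicates), 187 (folic acid in G3) and 817 (after folic acid) from male-labelled ones only, and 1916, 171, 38 and 17 from the 2 compared groups only. Library weights gave 809, 780, 1309, 2279 and 1044, no mean-variance trend 29, 3, 1, 54 and 15, DESeq2 930, 245, 215, 658 and 400, and edgeR 456, 18, 27, 261 and 117. After vehicle, no filter on low values gave 27 and quantile scaling 9, and for folic acid in G3 a mean of at least 50 gave 3, with fewer genes tested. Quantile scaling split calls 7 higher and 7 lower for folic acid in G3 (8 and 4 by limma with the labelled sex), and edgeR split the 456 in WT 306 and 150 (191 and 179). The series of title numbers, a possible batch that the labels do not name, gave 5, 0, 0, 0 and 4 (2514, 537, 937, 630 and 1224 unadjusted by limma). Outside folic acid in WT the series nearly repeat the groups, so these counts cannot tell batch from group there.

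The Y share gave 1, 9, 1, 17 and 2 genes, with TMM 1, 9, 1, 13 and 1, with quantile scaling 0, 8, 1, 15 and 2 (614 unadjusted for the 0), with edgeR 1, 7, 1, 12 and 1, and with DESeq2 4, 48, 11, 96 and 16. Without the 2 libraries of mixed RNA it gave 2, 3, 1, 31 and 0 (562 unadjusted for the 0), of which 0, 0, 0, 23 and 0 were among the genes called with the labelled sex, and without WT folic acid 1 0, 129, 1, 54 and 3 (540 unadjusted for the 0). The labelled sex without the 2 libraries gave 533, 13, 39, 598 and 433.

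Leaving out 1 library gave 1 to 1077 genes for folic acid in WT: 12, 886, 5 and 4 without WT vehicle 1 to 4, 1, 123 and 21 without WT folic acid 1 to 3, 203 and 14 without G3 vehicle 2 and 3, and 147, 879, 1077 and 16 without G3 folic acid 1 to 4. For folic acid in G3 the range was 2 to 275: 5, 4 and 5 without WT vehicle 1, 3 and 4, 275, 4 and 5 without WT folic acid 1 to 3, 5, 3, 2 and 5 without G3 vehicle 1 to 4, and 4, 158, 166 and 4 without G3 folic acid 1 to 4. After vehicle it was 1 to 321: 1, 127, 1 and 1 without WT vehicle 1 to 4, 1 without each WT folic acid library, 41, 2, 1 and 10 without G3 vehicle 1 to 4, and 321, 162 and 1 without G3 folic acid 2 to 4. After folic acid it was 20 to 445: 167 and 445 without WT vehicle 1 and 2, 35 and 20 without WT folic acid 2 and 3, and 20, 410 and 96 without G3 folic acid 1 to 3. For the interaction it was 6 to 570: 38, 439, 38 and 38 without WT vehicle 1 to 4, 14, 56 and 42 without WT folic acid 1 to 3, 6 and 68 without G3 vehicle 3 and 4, and 12 and 570 without G3 folic acid 1 and 2.

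Directions reversed mostly with the Y share and without the 2 libraries of mixed RNA. There the Y share varied within a group mainly in G3 folic acid (0.800 and 0.771 in libraries 1 and 3, 0.0173 in library 2). The Y term of that fit thus rests largely on these libraries, and whether it carries over to WT was not tested. For folic acid in WT the reversed directions were Slco1a1 (log2 2.38), Acsm3 (2.19), Cyp2j13 (1.30), Ugt2b37 (1.30), Cyp4b1 (1.30), Ugt2b38 (0.95), Cyp2e1 (0.39), Odc1 (0.0272) and the male kidney list (median 1.04). After vehicle these were Cyp2j13 (0.38), Ugt2b37 (0.54) and the male kidney list (1.30), after folic acid Cyp4b1 (-0.0505), and for the interaction Slc7a13 (-2.81), Slco1a1 (-2.56), Cyp2j13 (-0.71), Ugt2b37 (-0.51) and the male kidney list (-0.82). Pcolce2 in WT was log2 -0.00433 with the Y share in edgeR and -0.00464 in DESeq2. The macrophage list was -1.07 after folic acid and -0.91 for the interaction in female-labelled libraries only, where WT folic acid 1 stands alone for its group, and -0.40 for folic acid in WT without WT folic acid 1, the lowest of 15 fits with 1 library left out, of which the highest was 1.41 without WT folic acid 3.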

Other observations

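Among lists not described so far, none of the telomere and DNA damage genes passed over all genes and camera did not pass the list in any comparison (camera adjusted p by limma 0.760 and 0.968 for folic acid in WT and G3, 0.867 and 0.684 for G3 against WT after vehicle and after folic acid, 0.8996 for the interaction). Adjusted over the list alone, the shelterin gene Tinf2 (log2 -0.89) and the telomerase partner Nhp2 (-1.10) were lower in G3 vehicle than in WT vehicle, 2 of 20 members (0 over all genes). WT vehicle held the most Y-linked RNA and G3 vehicle almost none, so these 2 differences cannot be fully parted from sex. Folate and one-carbon genes did not pass as a list either (0.346, 0.123, 0.867, 0.870 and 0.911 in that order), with Shmt2 lower after folic acid in WT (log2 -1.38, 1 of 20, also over all genes), Shmt1 (-0.57) and Bhmt (-2.58) lower after folic acid in G3, and Cbs lower in G3 vehicle (-1.76), adjusted over the list alone. Antioxidant genes of the NRF2 pathway went both ways, adjusted over the list alone. In WT after folic acid Nqo1 (-1.38) and Srxn1 (-0.54) fell and Gsta2 (1.46) and Gsta4 (1.76) rose. Nqo1 was higher (1.34) and Gsta4 lower (-1.72) in G3 than in WT after folic acid. Among these antioxidant genes only Nqo1 passed over all genes, in both comparisons. With the Y share neither Shmt2 nor Nqo1 was called for folic acid in WT.

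Epithelial junction genes changed in 1 of 19 members with folic acid in WT (Cldn7, log2 1.12, adjusted over the list alone) and in 0 of 19 in G3, with camera adjusted p of 0.365 and 0.349 by limma. Of the TGF-beta response genes Tgfb2 (1.82) rose in WT and Ltbp2 (2.93) and Tgfbr2 (0.83) in G3, adjusted over the list alone, with camera adjusted p of 0.162 and 0.0780. In the podocyte list Cdkn1c was higher after folic acid in WT (1.01) and in G3 vehicle (0.91), in the loop and distal list Umod was higher in WT after folic acid (1.05) and Egf (-1.05) and Slc12a1 (-0.96) were lower in G3 than in WT after folic acid. Ighm of the B and plasma cell list rose with folic acid in G3 (1.12) and Fosb of the immediate early list was lower in G3 vehicle (-2.95), all adjusted over the list alone. Of these, Cldn7, Umod, Egf, Slc12a1 and, in WT, Cdkn1c also passed over all genes. With the Y share Pzp was the only gene called for folic acid in WT, so Cldn7, Umod and Cdkn1c were not called there. With the labelled sex, camera passed none of the 6 lists from epithelial junction to immediate early genes in any comparison. With the Y share, TGF-beta response genes (limma camera adjusted p = 0.00163), B and plasma cell genes (0.0487) and folate genes (0.0276) passed for folic acid in G3 at the preset correlation, and none of the 3 at the estimated correlation (0.202, 0.541 and 0.337). The muscle and adrenal lists had 1 tested member each.

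The tests of genes that separate the genotypes were chosen after the result was seen, and the test of residual blood before. In 59 genes all 8 G3 libraries lay on 1 side of all 7 WT libraries, 21 higher and 38 lower in G3, where chance gives 4.55. Over all 6435 splits of the 15 libraries into groups of 7 and 8, 48 gave as many, the real one counted, and the highest other split gave 366. Some splits that cross the genotypes thus separated more genes, so the 59 need not all reflect genotype. Of the 59 genes 8 lie on chromosome 13, which carries Tert (13.6 percent, against 3.86 percent of other tested genes, Fisher's exact p = 0.00196, two-sided), and 7 of the 8 were lower in G3: Agtpbp1, Col4a3bp, Fam208b, Hist1h4i, Mrps27, Mterf3, Nsa2 and Zfp953 are the 8. The 8 start at 3566035 (Fam208b), 22040636 (Hist1h4i), 59445742 (Agtpbp1), 66906968 (Mterf3), 67339306 (Zfp953), 96542618 (Col4a3bp), 97129424 (Nsa2) and 99344786 (Mrps27), and Tert at 73626911. Fisher's test takes genes as independent, which genes on the same chromosome need not be. DNA of the targeted parent strain linked to Tert may explain some of the 8, and neither their distance from Tert nor the strain of the mice was tested. With WT folic acid 1 placed in G3, 109 genes separated the genotypes (7 on chromosome 13), with G3 vehicle 1 placed in WT 118 (5), and with both exchanged 149 (6).

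Lower haemoglobin RNA in G3 folic acid could come from less blood left in the perfused kidney, in which case erythroid and neutrophil RNA should fall together within groups. Neutrophil RNA was scored by S100a8, S100a9 and Retnlg only, the neutrophil genes that fell with folic acid in G3. Over the 15 libraries the deviations from group means gave Pearson r = 0.274 (permutation p = 0.298, two-sided) and Spearman rho = 0.257 (permutation p = 0.351), and r = 0.357 without the 2 farthest libraries. That r lay under the bound set beforehand, but its 95 percent interval, added after r was seen, reached 0.690, so less blood and less erythroid RNA of other origin cannot be told apart here.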
